A study of Mus musculus with 6 samples.

How the data were processed

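Polyadenylated RNA was sequenced from cells of mouse fetal kidneys at embryonic day 18.5. The embryos carried a Six2-GFP transgene, whose fluorescence marks the cap mesenchyme, the progenitor tissue of the nephron. Per the labels' protocols, dissociated cells were sorted by flow cytometry into a GFP-positive fraction (Six2-high) and a GFP-negative fraction (Six2-low), with scatter gates against red blood cells, and the gate was set on kidneys without the transgene. There were 3 libraries per fraction. The titles tie each Six2-high library to 1 Six2-low library of the same preparation, by a date tag and the RNA purification kit. Replicate 1 has the first date tag and the TRI kit, and replicates 2 and 3 share a later date tag, with the Norgen kit for replicate 2 and the TRI kit for replicate 3. Whether replicates 2 and 3 came from separate animals is not given in the sources used here. The p-values of the comparison of fractions, fitted without pairing, measure the spread between the libraries of each fraction. That spread holds differences between preparations that both fractions share, and it may in part be technical. A fit with the preparation as a replicate block, given as an alternative, takes such shared differences out.

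The deposited tables hold raw gene counts and a normalised version of them, for 23420 gene symbols and 6 libraries. The submitters' processing notes name TopHat2 2.1.0, TopHat, SAMtools, HTSeq 0.6.1p1, DESeq2 and build mm10, without their roles. The annotation and whether counting used strand are not given in the sources used here. The deposited normalised signal equals the counts divided by DESeq2-type size factors, which were recomputed from the counts and agreed within 0.000564% for genes above 1000 counts. No row lacked a gene name, and 3662 genes had no counts. Total counts ran from 23535399 to 29791421 per library. The globin genes Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2 had 0 counts in every library, so erythroid content was read from the other members. Genes that share exons cannot be separated without strand: among 55 named genes with coordinates, 3 (Csf1r, Mcm7 and Pfkp) share exon positions with a gene at 0.1 of their own level or more, and their values are uncertain for that reason.

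Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries scaled by TMM, and fractions compared with the quasi-likelihood F test without a block, two-sided, with Benjamini-Hochberg adjusted p under 0.05. Levels are CPM, computed by edgeR on the TMM-scaled library size, given as mean ± SD over 3 libraries, and log2 fold changes are Six2-high minus Six2-low with their standard error (SE). Fixed gene lists, 24 with 551 members, were written from textbook knowledge before the data were examined. Of these members 548 were in the table, 3 of them under another symbol, and 513 were tested. Each list was compared with the other tested genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. An estimated correlation and fry, which asks whether the genes of a list move on balance one way, were alternatives. Kit and date were compared in an additive model of fraction and preparation, where the 2 fractions of a preparation stand as replicates, and the fraction by kit interaction in a model of its own. Named genes followed a rule also fixed beforehand. It takes Six2 and Cited1. It takes the 5 largest positive and 5 largest negative log2 fold changes among genes with adjusted p under 0.05, a mean of at least 10 CPM and the same direction in 3 preparations, leaving out predicted-gene symbols. It takes the 2 members with the smallest p in each list, and the 3 genes with the smallest p in each kit, date or interaction contrast with any call. Values of 2 genes that the rule takes are not reported here. Any other gene named in the text was chosen after its values were seen. For genes with 1 to 3 counts in a fraction the ratio of summed counts is given with its exact (Clopper-Pearson) 95% interval, which, like the other count intervals here, covers counting error only. Members at 0 in every library of a fraction numbered 2, and setting them at the bound given by 3 counts over the fraction changed the median of 0 lists. Coordinates are from the GENCODE M21 annotation on mm10.

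The preparations pair the libraries: the labels give the shared preparation, and deviations from the fraction means, across genes, correlated at 0.37, 0.42 and 0.33 within the 3 preparations. Every other pairing had a negative correlation, which taking deviations from a mean of 3 libraries largely forces and which adds no support. Genes are not independent replicates. Replicates of a fraction differed beyond sampling noise, with chi-square per degree of freedom from 16.9 to 213.

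The tests were run on 10 simulated data sets with 200 changed genes each, drawn from the real means, library sizes and dispersions. For the date, kit and interaction tests the dispersions were those of the additive model. For the comparison of fractions, over 15210 genes, 10.6% of 1.5-fold, 59.4% of 2-fold and 90.9% of 4-fold changes were recovered, and 6.89% of calls were unchanged genes. That share was 10.1% for the date contrast, 10.8% for the kit contrast and 15.6% for the interaction. In every gene comparison, that of fractions included, it lay above the 5% that the adjustment aims at. Marginal calls in data like those simulated are thus less sure than their adjusted p. The real comparison of fractions called 7686 of 15347 tested genes, far more than the 200 changed in each simulated set. Its recovery and its share of unchanged genes among calls may therefore differ from the simulated values, and were not estimated. In the list test, the list shifted by 1 log2 unit was called every time and a mean of 0.20 of 23 unshifted lists was called, with genes drawn independently of each other, which real lists are not. A single simulation was run at first, and the number was raised to 10 once its shares were seen to exceed the aim.

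Alternatives were DESeq2 size factors, no count filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, an adjusted p of 0.01, a test against a 2-fold change, leaving out each library and each preparation, summing the libraries that share a date, leaving out globin genes, limma on the deposited normalised values, and other list tests, prior counts and gene numbers. The ribosomal RNA related genes were left out, list members counted without Six2-high replicate 3, and kit and date contrasts run without each library after the data were seen.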

Results

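The transcriptomes of Six2-high and Six2-low cells from fetal mouse kidneys at embryonic day 18.5 were compared in 3 libraries per fraction. Total counts in Six2-high were 28466419, 24463268 and 23535399 for replicates 1 to 3. In Six2-low they were 25529817, 23995694 and 29791421. The libraries separated by fraction along the first principal component of the 500 most variable genes, which held 97.3% of their variance. In Six2-high replicate 3 the ribosomal RNA precursor Rn45s took 9.59% of counts (exact Clopper-Pearson interval 9.58 to 9.60) and Lars2 0.69% (0.684 to 0.691). In the other 5 libraries the highest shares were 0.68% (0.673 to 0.679) and 0.062% (0.061 to 0.062), both in Six2-high replicate 1.

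The comparison of fractions asks how nephron progenitors differ from the rest of the kidney. Six2, the transcription factor whose promoter drives the sorting marker, was at 1224 ± 332 CPM (SD, n = 3) in Six2-high and 15.2 ± 7.05 CPM in Six2-low, a log2 fold change of 6.33 (SE 0.39, edgeR quasi-likelihood adjusted p = 4.4e-06). Six2 lies on chromosome 17 from 85684277 to 85688274 on the minus strand. Its difference checks the sort and is not an independent finding. By preparation the log2 difference of Six2 was 5.18, 7.03 and 6.91 in replicates 1 to 3, so it was smallest in replicate 1. That of Cited1 was 3.56, 5.15 and 4.95. The cause was not tested. Cited1, a marker of the least differentiated progenitors (chromosome X, 102247381 to 102252181), was higher by 4.63 log2 units (SE 0.33, adjusted p = 8.4e-06), at 145 ± 54.0 against 5.84 ± 1.16 CPM.

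Of 15347 genes tested, 7686 differed between the fractions, 3285 higher and 4401 lower in Six2-high, and 8675 had an unadjusted p under 0.05. Losses in Six2-high were larger than gains: 1566 genes were lower by more than 3 log2 units and 151 higher by as much. The direction was the same in 3 preparations for 7677 of the 7686 genes. As these genes were called on the same libraries, this follows largely from the selection and is not replication. The fractions did not overlap in 9203 genes (60.0%), where chance gives 10%. Fold changes of single preparations correlated across genes, which are not independent replicates, at 0.93 to 0.97. Against a 2-fold threshold 3208 genes passed, 546 of them higher, and without both libraries of replicate 3 there were 4629, of which 1329 were higher. Genes higher numbered 2160 without Six2-low replicate 2 and 2086 without both libraries of replicate 2.

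Among genes with a mean of at least 10 CPM, the largest gains included Six2 and genes of varied function. Nxph1, encoding a secreted neurexin ligand (chromosome 6, 8948431 to 9249032), rose by 7.89 (SE 0.94, adjusted p = 0.00016), from 0.088 ± 0.12 to 23.6 ± 15.2 CPM, and by 9.94 without Six2-low replicate 3, which held 7 of its 8 counts in that fraction. Fgf20, a growth factor gene that maintains nephron progenitors (chromosome 8, 40279166 to 40308331), rose by 7.16 (SE 0.26, adjusted p = 5.4e-07), from 0.153 ± 0.0385 to 22.9 ± 2.89 CPM. Crym, encoding a thyroid hormone binding protein (chromosome 7, 120186380 to 120202111), rose by 5.57 (SE 0.31, adjusted p = 2.7e-06), from 6.78 ± 2.29 to 323 ± 86.7 CPM.

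In the same set, the 5 largest losses were in an epithelial splicing factor, a ureteric bud ligand and neutrophil genes. Esrp1, which directs epithelial splicing (chromosome 4, 11331933 to 11386783), was at 38.2 ± 2.93 CPM in Six2-low and had 2 counts in the 3 Six2-high libraries together, a ratio of 1383 with an interval of 383 to 11426. Wnt9b, the ureteric bud signal to the progenitors (chromosome 11, 103727364 to 103749821), also had 2 counts in Six2-high, a ratio of 905 (250 to 7478). Ltf, encoding lactoferrin of neutrophil granules (chromosome 9, 111019271 to 111042767), had 2 counts as well, a ratio of 862 (238 to 7126). Ngp (chromosome 9, 110419747 to 110423012) and S100a9 (chromosome 3, 90692632 to 90695721), also of neutrophils, had log2 fold changes of -9.19 (SE 1.10) and -9.14 (SE 0.68). Six2-low replicate 1 stood above replicates 2 and 3 in these neutrophil genes, at 48.2 against 10.6 and 13.1 CPM for Ltf, 131 against 22.0 and 24.8 for Ngp, and 68.1 against 24.8 and 30.8 for S100a9. Without it the log2 fold change of Ltf went from -9.54 to -8.56 and that of Ngp to -7.89, so the size of these 2 losses rests in part on 1 library, while S100a9 went to -10.55 without Six2-high replicate 1.

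**Figure D1:**
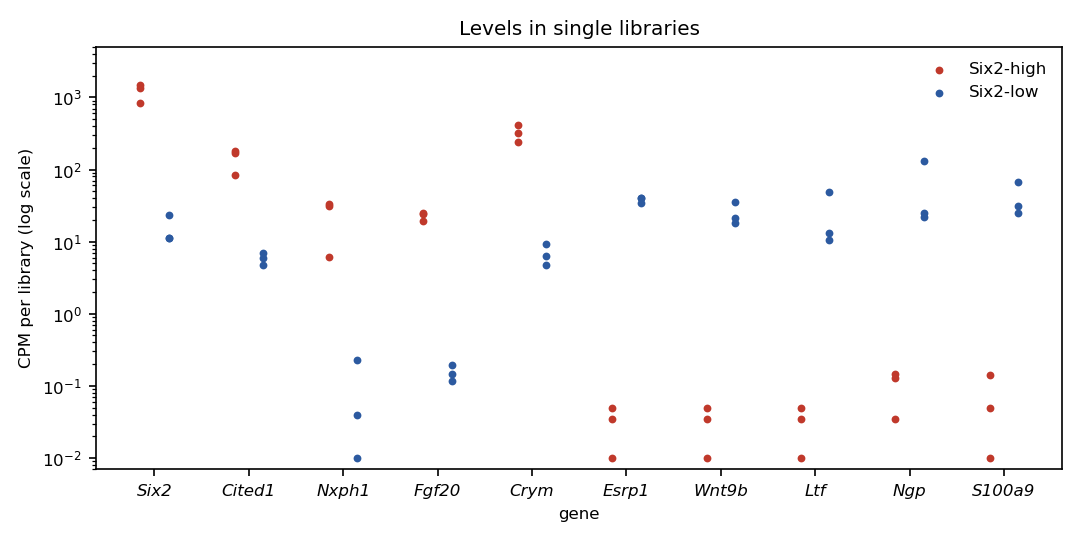
CPM per library on a log axis for 9 genes with large changes and for Cited1, with red points for Six2-high and blue points for Six2-low, 3 libraries each. Values below 0.01 CPM are drawn at 0.01, and the fractions do not overlap for any gene shown.

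Genes of the cap mesenchyme rose together. Of 26 tested members 23 were higher and 2 lower in Six2-high, also when adjusted over the list alone, with a median log2 fold change of 2.17. By preparation the list median was 1.67, 2.37 and 2.33 log2 units in replicates 1 to 3. Fgf20 and Spock2, a matrix proteoglycan gene, had the smallest p, and Spock2 reached 1284 ± 297 CPM against 56.3 ± 9.22 (log2 fold change 4.51, SE 0.22). Dapl1 and Fgf9 were the lower members, and without Six2-high replicate 3 neither passed (0 members lower), though both passed with the replicate block (adjusted p = 0.019 and 0.0031). The list was higher by camera (adjusted p = 2.1e-10), but adjusted p = 0.23 with an estimated correlation. Posterior Hox genes and receptor tyrosine kinase response genes were the other lists called higher. Of 9 Hox genes of paralog groups 9 to 13, 7 were higher and 1 lower (7 and 2 adjusted over the list alone, and with the replicate block). The lower member, Hoxd9, did not pass without Six2-high replicate 3 (adjusted p = 0.063) but did with the replicate block (adjusted p = 0.0020). The smallest p were those of Hoxd12 at 63.2 ± 1.95 against 1.66 ± 0.34 CPM (5.26, SE 0.18) and Hoxc9 (1.96, SE 0.11). Of 19 response genes 8 were higher and 1 lower, with the same numbers adjusted over the list alone, and 10 and 2 with the replicate block. Il17rd, a feedback inhibitor of FGF signalling, and the receptor gene Fgfr1 both rose by 1.44 (SE 0.11 and 0.14). Camera gave adjusted p = 0.0012 for the Hox list and 0.0043 for the response list, and adjusted p = 0.23 and 0.39 with an estimated correlation.

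Markers of differentiated nephron segments fell. All 24 tested proximal tubule members were lower, with a median log2 fold change of -3.61. Slc7a9, an amino acid transporter gene, was at -4.31 (SE 0.18) and Hnf4a, a transcription factor gene, at -5.17 (SE 0.26). Of 23 loop of Henle and distal tubule members 19 were lower and 2 higher (median -6.55), with Mal at -7.22 (SE 0.17) and Sim2 at -8.05 (SE 0.25). Of 17 podocyte members 13 were lower and 1 higher (median -3.37), with Podxl, encoding podocalyxin, at 5.05 ± 2.05 against 446 ± 27.9 CPM and Ptpro, a podocyte phosphatase gene, at -3.25 (SE 0.14). These counts were the same adjusted over each list alone, and each list was lower by camera (adjusted p = 2.5e-11, 6.5e-08 and 2.2e-05) but not with an estimated correlation (adjusted p = 0.23 for each). Of 19 early nephron members 11 were lower and 2 higher, or 12 and 2 adjusted over the list alone (median -1.49, adjusted p = 0.014, and adjusted p = 0.63 with an estimated correlation). Bmper, encoding a BMP binding protein, rose by 4.29 (SE 0.24) and Wnt4, an early signal of nephron formation, by 1.82 (SE 0.20).

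Ureteric bud and collecting duct genes were lower in 23 of 24 members and higher in 1 (median -5.87). Scnn1b, a sodium channel subunit gene, and Ret, the receptor of ureteric tips, had log2 fold changes of -7.97 (SE 0.23) and -6.55 (SE 0.20). This was the only list called by camera with both correlations (adjusted p = 2.5e-11, and adjusted p = 0.035 with an estimated correlation). Epithelial junction and polarity genes were lower in 26 of 27 members (median -4.87), with Cldn8 at 0.278 ± 0.066 against 84.3 ± 3.48 CPM and St14 at 1.57 ± 0.20 against 99.7 ± 3.90 CPM (camera adjusted p = 6.0e-15, and adjusted p = 0.15 with an estimated correlation). The counts of both lists held adjusted over the list alone.

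Genes of other lineages were also lower in Six2-high. Endothelial genes were lower in 20 of 21 members and higher in 1 (median -6.51), with Robo4 at -8.07 (SE 0.28) and Kdr, the VEGF receptor gene, at -7.27 (SE 0.27). Immune genes were lower in 20 of 22 (median -6.17), among them C1qb at -6.24 (SE 0.20) and Csf1r at -6.27 (SE 0.20), the latter sharing exons with Hmgxb3. Stromal genes were lower in 23 of 27 and higher in 3 (median -3.46), with Dcn at -3.90 (SE 0.13) and Postn at -4.84 (SE 0.26). Foxd1, the stromal progenitor marker, was higher at 107 ± 52.1 against 42.5 ± 20.8 CPM (log2 fold change 1.33, SE 0.48, adjusted p = 0.046), but not without Six2-high replicate 3 (adjusted p = 0.17). Within preparations it was higher each time, at 49.3 against 18.7, 120 against 51.5 and 151 against 57.3 CPM in replicates 1 to 3, and with the replicate block adjusted p = 2.5e-05, as its level differed between dates. Smooth muscle and pericyte genes were lower in 11 of 16 and higher in 2, or 12 and 2 adjusted over the list alone, and without Six2-high replicate 3 only 1 was higher, as Mcam did not pass (adjusted p = 0.058, against 0.013 with the replicate block). Pdgfrb fell by 3.21 (SE 0.22) and Des, encoding desmin, rose by 3.62 (SE 0.20). Mesenchymal genes were lower in 17 of 23 and higher in 4, or 17 and 5 adjusted over the list alone. Thy1 fell by 4.62 (SE 0.20) and Cdh2, encoding N-cadherin, rose by 2.55 (SE 0.11). Camera called these 5 lists lower (adjusted p = 2.7e-10, 3.7e-11, 3.4e-06, 0.0058 and 0.0013, in that order). With an estimated correlation none of them passed (adjusted p = 0.23 for the endothelial, immune and stromal lists, 0.40 for smooth muscle and 0.39 for mesenchymal genes). The endothelial, immune and stromal counts held adjusted over the list alone.

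Erythroid genes were lower in 4 of 5 tested members (5 adjusted over the list alone), but the list did not pass (adjusted p = 0.095), and Beta-s, a beta globin gene, varied in Six2-low at 574 ± 775 CPM (1468 in replicate 1, 127 in each of the others) against 9.64 ± 5.95 in Six2-high. The erythroid list passed without Six2-low replicate 1 (adjusted p = 0.020) or replicate 2 (adjusted p = 0.048), and without both libraries of replicate 1 (adjusted p = 0.014), with a range of 0.014 to 0.62 over 15 alternatives. The other erythroid gene named by the rule, Epb4.2, had a log2 fold change of -5.55 (SE 1.12), with -4.09 without Six2-low replicate 1 and -6.60 without Six2-high replicate 3. Nerve, glia and adrenal genes went both ways, 4 higher and 5 lower of 11 (4 and 6 adjusted over the list alone, adjusted p = 0.95), with Elavl4 at 4.15 (SE 0.28) and Stmn2, both neuronal genes, at -4.70 (SE 0.78), or -8.58 without Six2-high replicate 1, the only library of that fraction with counts of it.

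**Figure D2:**
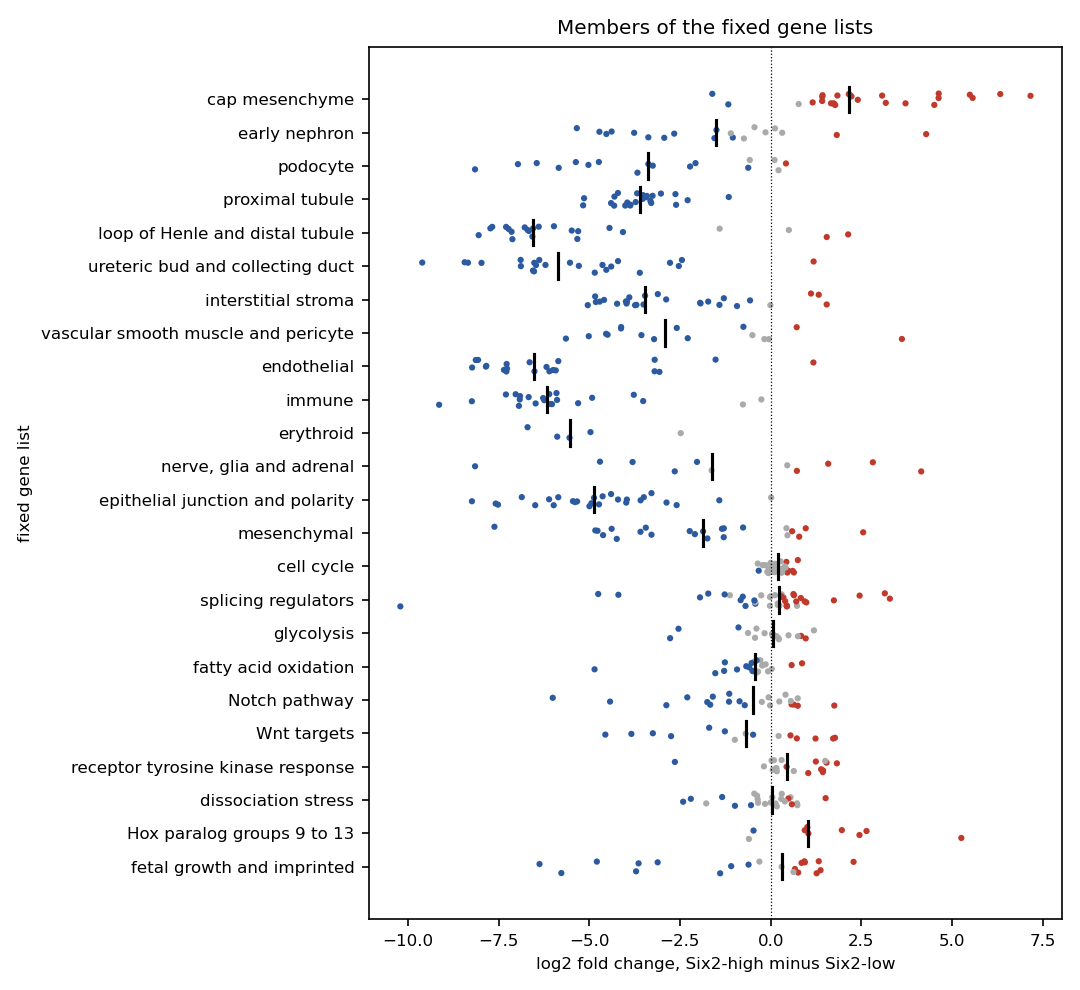
Log2 fold change, Six2-high minus Six2-low, of every tested member of the 24 fixed lists. Points are red where higher, blue where lower and grey where the test was not passed at an adjusted p of 0.05, and black bars are list medians, at 2.17 for the cap mesenchyme and -6.55 for the loop and distal tubule list.

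Splicing regulators changed in both directions, 17 higher and 11 lower of 40 (18 and 12 adjusted over the list alone). Rbfox1, a regulator of muscle and neural splicing, rose by 3.29 (SE 0.18), opposite to Esrp1. The list did not pass (camera adjusted p = 0.21). Its median was 0.22 while its mean was -0.23, and fry gave a lower direction without passing (adjusted p = 0.54). Cell cycle genes were nearly level, with 7 higher and 1 lower of 35, and 1 and 0 adjusted over the list alone. Mcm7, a replication licensing gene that shares exons with Cops6, was at 388 ± 38.3 against 249 ± 17.4 CPM (0.64, SE 0.12), and Cenpf, a kinetochore gene, differed by 0.47 (SE 0.14, adjusted p = 0.021). Cenpf did not pass without Six2-low replicate 2 (adjusted p = 0.079) or 3 (adjusted p = 0.078), without both libraries of replicate 2 (0.11) or 3 (0.11), or with same-date libraries summed (0.088). Over 21 alternatives its adjusted p ranged from 0.0031 to 1.00, the latter against a 2-fold change. The cell cycle list did not pass (adjusted p = 0.054, and adjusted p = 0.80 with an estimated correlation) but did with the replicate block at the preset correlation (adjusted p = 0.023), which called 17 members higher and 2 lower. Without Six2-high replicate 3 the list passed (adjusted p = 0.040) with 3 members higher, and it also passed without Six2-high replicate 2 (adjusted p = 0.0039) or Six2-low replicate 1 (adjusted p = 0.0072), or without both libraries of replicate 2 (adjusted p = 0.021). Over 15 alternatives its adjusted p ranged from 0.0039 to 0.80.

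Fatty acid oxidation genes were lower in 12 of 23 members and higher in 2, or 13 and 2 adjusted over the list alone. Ppargc1a, a coactivator of mitochondrial genes, fell by 4.85 (SE 0.38) and Acadm, an acyl-CoA dehydrogenase gene, by 1.26 (SE 0.13). Camera gave adjusted p = 0.022, adjusted p = 0.60 with an estimated correlation, and adjusted p = 0.093 without Six2-high replicate 2, in a range of 0.0038 to 0.60 over 15 alternatives. Glycolysis genes did not pass as a list (adjusted p = 0.95), with 2 higher and 3 lower of 19, the same adjusted over the list alone, and 7 and 6 with the replicate block. Its median was 0.063 and its mean -0.14, and fry gave a lower direction without passing (adjusted p = 0.48). Pfkp, which shares exons with the more highly counted Pitrm1, and Slc2a3, a glucose transporter gene, were at -2.77 (SE 0.18) and -2.54 (SE 0.26).

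Among signalling lists, Notch pathway genes were higher in 4 and lower in 11 of 22 (5 and 11 adjusted over the list alone, 7 and 12 with the replicate block). Notch4 and Dll4, both of endothelium, were at -2.88 (SE 0.17) and -6.01 (SE 0.38). Wnt target genes were higher in 5 and lower in 7 of 15 (5 and 9 adjusted over the list alone), with Rnf43 at -4.56 (SE 0.19) and Lgr5 at -3.25 (SE 0.19). Neither list passed camera (adjusted p = 0.18 and 0.45), while fry gave adjusted p = 0.0016 for both, toward lower values. Dissociation stress genes were higher in 3 and lower in 5 of 25, the same adjusted over the list alone, and 8 and 9 with the replicate block (camera adjusted p = 0.95). The list median was 0.046 and its mean -0.20, and fry gave a lower direction without passing (adjusted p = 0.47). Ier3 and Klf6 were at -2.41 (SE 0.16) and -2.20 (SE 0.20). Fetal growth and imprinted genes were split, 9 higher and 9 lower of 21, also adjusted over the list alone (camera adjusted p = 0.95). Asb4 and Peg10 were at -6.37 (SE 0.31) and -3.71 (SE 0.20). The list median was 0.30 and its mean -0.93, and fry gave a lower direction (adjusted p = 0.017).

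In total camera called 3 lists higher and 12 lower. With an estimated correlation 1 list passed.

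The date contrast compared the TRI preparations of the first and the later date, within fractions. Each date has 1 such preparation, so the SE and p of this contrast come from how far the 2 fractions of a preparation disagree, not from spread between preparations of a date. It called 118 genes, 61 higher and 57 lower at the first date, with 3293 at an unadjusted p under 0.05. On simulated data 10.1% of such calls were unchanged genes. Xist, the noncoding RNA of the inactive X chromosome, was at 346 CPM at the first date and 1140 at the later one, a log2 difference of -1.72 (SE 0.07, adjusted p = 0.0042). Btg2, an early response gene, was higher by 1.58 (SE 0.08) and Pdk1, a kinase gene induced by low oxygen, lower at -2.20 (SE 0.12), both with adjusted p = 0.0054. Of the dissociation stress list 11 of 25 members were higher at the first date, and of the glycolysis list 9 of 19 were lower. Adjusted over the list alone they were 16 higher and 14 lower. Camera called 12 lists between dates and 0 with an estimated correlation, these lists among the 12 (adjusted p = 2.2e-10 and 1.6e-10, and adjusted p = 0.21 for each with an estimated correlation). Camera also called, toward higher values at the first date, the cell cycle (adjusted p = 1.8e-09), endothelial (2.0e-05), early nephron (8.7e-05), nerve, glia and adrenal (0.00074), smooth muscle and pericyte (0.013), mesenchymal (0.030), immune (0.033) and erythroid (0.047) lists, and toward lower values the proximal tubule (5.7e-05) and fetal growth and imprinted (0.00065) lists. Few of their members passed singly: 1 cell cycle, 1 endothelial and 1 fetal growth gene, and 0 in each of the other 7 lists. Adjusted over the list alone, 24 of 35 cell cycle, 16 of 21 endothelial, 9 of 19 early nephron, 0 of 11 nerve, glia and adrenal, 3 of 16 smooth muscle, 3 of 23 mesenchymal, 5 of 22 immune and 5 of 5 erythroid members were higher, 6 of 24 proximal tubule members were lower, and of 21 fetal growth genes 5 were lower and 1 higher. The Y-linked genes Kdm5d, Eif2s3y, Ddx3y and Uty, chosen after their values were seen, were higher at the first date by 3.30 (SE 0.21), 3.22 (SE 0.21), 2.75 (SE 0.19) and 3.28 (SE 0.29) log2 units. In Six2-high replicates 2 and 3 Kdm5d was at 2.53 and 2.65 CPM and Eif2s3y at 2.74 and 1.82, against 31.7 and 20.1 CPM in replicate 1. This leaves open that replicates 2 and 3 share animals, which was not tested. The count rests on single libraries: it was 0 without Six2-high replicate 3, 4 without Six2-low replicate 3, 49 and 52 without Six2-high and Six2-low replicate 2, and 3457 and 4057 without Six2-high and Six2-low replicate 1.

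The kit contrast compared Norgen with TRI on the shared date, again with 1 preparation each. It called 0 genes by edgeR, with 2889 at an unadjusted p under 0.05, and 588 by DESeq2. It too rests on single libraries, with 4015 calls without Six2-high replicate 1, 4035 without Six2-low replicate 1 and 3 without Six2-low replicate 3. The fraction by kit interaction called 0 genes by edgeR (148 at an unadjusted p under 0.05) and 0 by DESeq2, with 1 Norgen library per fraction, assumed to vary like the TRI libraries. Its model has no term for preparation. The TRI preparations of different dates thus stand as replicates, and their difference widens the spread and can hide an interaction. In simulated data this test recovered 75.5% of 4-fold and 23.7% of 2-fold changes. Those data had the dispersion of the additive model and no difference between dates, so the real test may recover less.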

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

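The median log2 difference of the glycolysis list had another sign in the Norgen preparation, at -0.023, than in the TRI preparations, at 0.18 and 0.13. The difference of this list median between kits was not tested, each value rests on 1 pair of libraries, and the list did not pass in the comparison of fractions.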

How the results depend on the processing

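The alternatives for the ribosomal RNA related genes, for list members, and for kit and date without single libraries were chosen after the data were seen. No gene called in the comparison of fractions changed sign under any setting for genes, and 8 of 1193 values of named genes fell short of the threshold, those of Cenpf and Mcm7. Most named genes were picked for large fold changes or small p in these same libraries, so this follows largely from the selection. The count of 7686 genes stayed within 1.5 times except against a 2-fold change (3208, with 546 higher and 2662 lower) and without both libraries of replicate 3. Over single libraries and preparations left out it ran from 4629 to 7710, and genes higher in Six2-high ran from 1329 to 3183, below the 1.5 times limit without Six2-low replicate 2 (2160) and without both libraries of replicate 2 (2086). Genes higher were 1812 at an adjusted p of 0.01 and 1995 with same-date libraries summed, which leaves fewer samples. The replicate block gave 9919 genes, 4860 higher and 5059 lower, with 7661 shared in the same direction, and among list tests it changed only the call of the cell cycle list, apart from member counts given with the lists. With an estimated correlation 0 lists were called higher and 1 lower. The fetal growth and imprinted list, not called by camera, was called in the other direction by fry (adjusted p = 0.017); the cause was not tested. DESeq2 called 588 genes between kits and 749 between dates. The edgeR counts of 0 and 118 ran from 0 to 4035 and from 0 to 4057 without single libraries, in fits with 1 residual degree of freedom. The first principal component held 95.5% of variance over 2000 genes, 90.1% over all tested genes and 96.7% on the deposited normalised values. Depth limits genes such as Esrp1, whose 2 counts in Six2-high leave its ratio open between 383 and 11426.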

Other observations

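All tests below were chosen after the results were seen, except those of small RNA genes, histone genes and overlapping genes, which were written beforehand. The genes named here were chosen after their values were seen.

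Some genes known from striated muscle or cartilage, 9 of them picked for their high values and not from a fixed list, were higher in Six2-high. Des was at 154 ± 27.1 CPM (SD, n = 3), Actn3 at 39.0 ± 10.7, Colq at 27.4 ± 12.8 and Atp2a1 at 26.8 ± 12.3, with edgeR log2 fold changes of 3.62, 4.36, 3.83 and 4.36 in that order. Col2a1, the main collagen of cartilage, was at 604 ± 94.8 CPM against 51.7 ± 13.96 in Six2-low (log2 fold change 3.55, adjusted p = 4.3e-06), and Col9a1, Col11a2 and Matn1 were higher by 4.15, 3.12 and 5.51. Other genes of these tissues went both ways at mostly low levels. Tnnt3 was at 12.5 CPM in Six2-high against 4.45 in Six2-low, Tnni2 at 1.41 against 0.479, Myl1 at 0.627 against 0.012, Neb at 1.27 against 0.739 and Lect1 at 2.91 against 1.09, whereas in Six2-high Acta1 was at 1.16 ± 0.72 CPM, Myod1 at 0.016 ± 0.028 and Acan at 0.138 ± 0.010, and the cartilage genes Hapln1, Col9a3 and Col9a2 were at 0.517, 0.986 and 3.03 CPM in Six2-high against 13.2, 9.55 and 5.35 CPM in Six2-low.

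The levels of marker transcripts argue against muscle or cartilage cells as the source of these 9 genes. The median of 16 muscle transcripts, Myod1 and Myog among them, was 0.41 CPM in Six2-high, against 27.4 CPM for the muscle genes of the pattern. The median of 10 cartilage transcripts was 0.48 CPM against 44.9 CPM. As the pattern genes were picked for their high values, lower medians of other transcripts were likely, and a small share of such cells is not excluded. Of the 16 and 10 transcripts, 15 and 9 lay under 0.1 of those medians, with Tnnt3 at 12.5 CPM and Sox9, which kidney cells also express, at 34.5 CPM as the exceptions. Reads of overlapping genes could account for 1 of the 9 genes tested, Atp2a1, which shares exons with Rabep2 at 47.0 CPM. Expression of these genes by the Six2-high cells themselves remains open as a hypothesis, found and tested on the same data, and GC content and gene length were not tested.

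Proximal tubule markers kept a median of 7.72% of their Six2-low level in Six2-high, whereas endothelial markers kept 1.09%, ureteric and collecting duct markers 1.11% and loop and distal tubule markers 0.99%. This is not particular to the proximal tubule, as podocyte markers kept 10.1%, stromal 9.06%, smooth muscle and pericyte 13.6%, mesenchymal 29.9% and early nephron markers 35.4%. Carry-over of all Six2-low cells at 1 rate is argued against as the whole cause, as it would leave every cell type at the same share. The 10 cell type lists with 174 members at 10 CPM or more differed (Kruskal-Wallis permutation p = 1.0e-05, the smallest the permutations can give, with genes taken as independent). They include the early nephron and stromal lists, which held members higher in Six2-high, so some difference was likely beforehand. The proximal tubule and endothelial medians lay 2.81 log2 units apart. GFP kept by cells of every nephron segment stays open: it would raise loop markers above ureteric ones by an unknown amount, and the difference of -0.24 has a bootstrap interval of -2.20 to 0.94. Cells of proximal tubule kind among the sorted cells may remain: 72.7% of the 22 members lay within 1 log2 unit of their median, between the 50% and 75% that would have argued against or for it, and such cells and low expression in progenitors cannot be told apart here.

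In Six2-high replicate 3 the high Rn45s went with other RNAs that lack a poly(A) tail, Rmrp at 81.2 CPM, Rpph1 at 22.1 CPM and Scarna2 at 5.11 CPM. Each of these was at most 1.22 CPM in Six2-high replicates 1 and 2. Counts assigned to Lars2, a protein-coding gene, were high as well. A change of the whole Six2-high group is argued against, since Rn45s in replicates 1 and 2 differed from Six2-low by 0.34 log2 units. Tests written beforehand split. Histone genes, whose mRNAs mostly lack a poly(A) tail, were higher in this library by a median log2 ratio of 1.40 over 55 genes (bootstrap interval 1.01 to 1.85). The most abundant of them, Hist1h1c, Hist3h2a, Hist3h2ba and Hist2h2be, had lower ratios of -0.15, 0.049, 0.38 and 0.21. The histone median thus rests mostly on genes at low CPM. The 56 other small RNA genes were level at -0.044 (-0.20 to 0.054). Retained non-polyadenylated RNA is therefore a candidate explanation for the histone and ribosomal RNA part. The small RNA genes tested did not rise as a set. Most were at low CPM, and whether the libraries keep RNAs this short was not tested. Rmrp, Rpph1 and Scarna2, already seen to be high, were left out of that test. Its level median thus gives no evidence for or against carry-over. Lars2, here counted among the ribosomal RNA related genes, rose nearly as much as Rn45s over Six2-high replicates 1 and 2 (log2 ratios 3.96 and 4.08). The cause of the Lars2 rise was not tested, nor was any biological explanation. Gene counts cannot tell Lars2 mRNA from other reads assigned to that gene.

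The 6 libraries make only 10 splits into groups of 3, so the share of splits with a result as large is never under 0.1. The split by fraction called 7686 genes and was the only 1 with as many, the highest other calling 0. For the fixed lists the split by fraction called 15, and 4 of the 10 splits called as many, the highest being 18 with Six2-high replicate 1 and Six2-low replicates 1 and 3 together. Among the splits that part 3 preparations, as the fractions do, the others called 8, 12 and 15 lists and 0 genes, and those that part 1 preparation called 6 to 18 lists and 0 genes. Every other split joins 2 libraries of a fraction with 1 of the other, so it carries part of the difference between fractions, which moves lists and widens the spread within groups, and its counts are not those of data without a difference.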
